A study of Mus musculus with 12 samples.

How the data were processed

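Peak lists from 9 of the 12 samples of the series were analysed: 3 NKX2-1, 3 H3K4me3, 2 PRDM16 and 1 PRDM3. The 3 IgG samples (2 rabbit and 1 sheep) were not analysed here, so no background library was set beside the peaks. Each reaction used 100000 cells, per the labels. Groups, replicate numbers and antibody hosts were taken from the labels. Trimmomatic, Bowtie2, MACS2 and HOMER and the build mm10 are named in the submitters' processing notes, without versions or settings. Peaks were deposited as 1 list per sample. Whether a control library entered the peak calling is not given in the sources used here.

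The deposited fold enrichment of a peak is a ratio of its signal to background as the authors' peak caller gave it. It was used to describe, rank or filter peaks within a list. It was also averaged over the NKX2-1 libraries to choose and describe named genes. Libraries differ in the scale of this value, so the SD of such a mean includes that difference. The deposited −log10 p and −log10 q values are also the authors'. The deposited score is 10 times the −log10 p for the factor lists, cut to a whole number, and 10 times the −log10 q for the H3K4me3 lists. From the values, factor lists reached down to p of about 0.01 and H3K4me3 lists to q of about 0.001. The factor lists thus hold many peaks of low confidence, and counts of peaks are not comparable between the 2 kinds of list. At q under 0.05 lay 44.5% and 45.0% of the PRDM16 peaks, 42.3% of the PRDM3 peaks, and 76.4%, 10.8% and 12.9% of the NKX2-1 peaks. Read depth is unknown, so no interval that needs it is given. The Wilson 95% intervals are over regions and cover counting error only.

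Peaks on chromosomes 1 to 19, X and Y were used. A PRDM16 region was a stretch covered in both libraries, an NKX2-1 or H3K4me3 region one covered in at least 2 of 3 libraries, each of at least 20 bases. The PRDM3 regions were its 1 library's peaks, with no replicate check. Regions overlapped when they shared at least 1 base. Distal regions overlapped no H3K4me3 peak of any library. Chance overlap came from shifting regions around each chromosome in 1000 draws, or 100 draws for pairs of single libraries, with two-sided p. Such shifts ignore that accessible chromatin clusters, so local shifts of 5 to 50 kb were an alternative.

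Gene positions came from RefSeq genes of GRCm38.p6, the assembly of mm10. The table used gives neither strand nor exons. The planned 5′ end was therefore replaced by either annotated gene end, and a region is described only as inside or outside a gene. A region was linked to the gene with the nearest end within 50 kb of its midpoint. An alternative with all annotated transcript starts could not be used for the same reason. The 4 motif results needed a genome sequence and were not run. Of the genes in 16 lists, 1 was not matched, Dnai1 in the ciliated list. Lists were tested over 21887 protein-coding genes with Fisher's exact test and Benjamini-Hochberg adjustment over 64 tests. Combined choices and region sets tested singly were adjusted over the 16 lists of that set. Lists overlap (Pdpn, Fasn, Hopx, Abca3, Lyz2 and others stand in more than 1), so their calls are not independent. Shares per library were compared with exact permutation tests, and fold enrichment of PRDM16 peaks with 100000 label draws over peaks.

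The lists, tests and most alternatives were fixed before the data were examined. Named genes followed a rule fixed then. They are Nkx2-1, Prdm16 and Mecom. In each list they are also up to 4 members with the highest mean NKX2-1 fold enrichment in a linked shared region, and up to 2 members, alphabetically, without a region. Genome-wide they are genes with the best mean rank over the 6 factor libraries, of which not all are named. Means use the NKX2-1 libraries with a peak in the region, and n gives their number, so regions without a peak in the weaker replicates 2 or 3 have higher means. Alternatives included stricter and equal-length peak lists, overlap of at least 50% of the shorter region, autosomes only, leaving out each library, other links and other gene backgrounds. The tests were tested on simulated data. For the overlap of PRDM16 with NKX2-1, 0 of 40 unrelated sets of 39386 regions had p under 0.05, and a planted overlap of 20% was found as 20.7%. These simulated regions were placed uniformly at random along each chromosome. They therefore give no false-positive rate for peaks that cluster in accessible chromatin. For the gene lists, over 21887 genes, 8 of 200 random lists and 200 of 200 lists with 18 of 20 genes linked had p under 0.05. The latter lists all had the same counts and thus the same p, so they give no detection rate. For PRDM16 peaks, over 111440 peaks, a planted log2 difference of 0.3 was found as 0.3. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0, statsmodels 0.14.6 and matplotlib 3.10.9 were used.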

Results

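Binding of 3 proteins and 1 histone mark was mapped by CUT&RUN, in which an antibody directs a nuclease to cut and release nearby chromatin. The cells were EpCAM-positive epithelial cells from pooled lungs of fetal wild-type mice at E17.5, when alveolar type 1 (AT1) and type 2 (AT2) cells are forming. NKX2-1 is the homeodomain transcription factor that specifies lung epithelium. PRDM16 and PRDM3 (encoded by Mecom) are related zinc-finger proteins, and H3K4me3 marks active promoters. Peak lists were analysed for 3 NKX2-1, 3 H3K4me3, 2 PRDM16 and 1 PRDM3 library. The 2 PRDM16 libraries used antibodies raised in rabbit (replicate 1) and sheep (replicate 2). The 3 IgG samples were not analysed here. It is not stated whether replicates came from separate animals or pools, so tests between libraries measure only the spread between these libraries. Read depth is unknown from peak lists. The PRDM16 lists held 111489 and 79072 peaks, and the PRDM3 list held 52283. The NKX2-1 lists held 52716, 62996 and 79511 peaks (65074 ± 13518, SD, n = 3). The H3K4me3 lists held 19117, 15583 and 14646 peaks (16449 ± 2358, SD, n = 3).

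The libraries differed in the strength of their peaks. With a −log10 q of at least 5, NKX2-1 replicate 1 had 12964 peaks, whereas replicates 2 and 3 had 668 and 1182. PRDM16 replicates 1 and 2 had 19489 and 11551 such peaks, PRDM3 had 4856, and the H3K4me3 libraries had 17863, 15157 and 14435. Peak names fell into a pair of letter series. The first held all PRDM16 and PRDM3 peaks and replicate 1 of NKX2-1 and H3K4me3. The second held replicates 2 and 3 of NKX2-1 and H3K4me3. This split was treated as a possible batch.

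**Figure D1:**
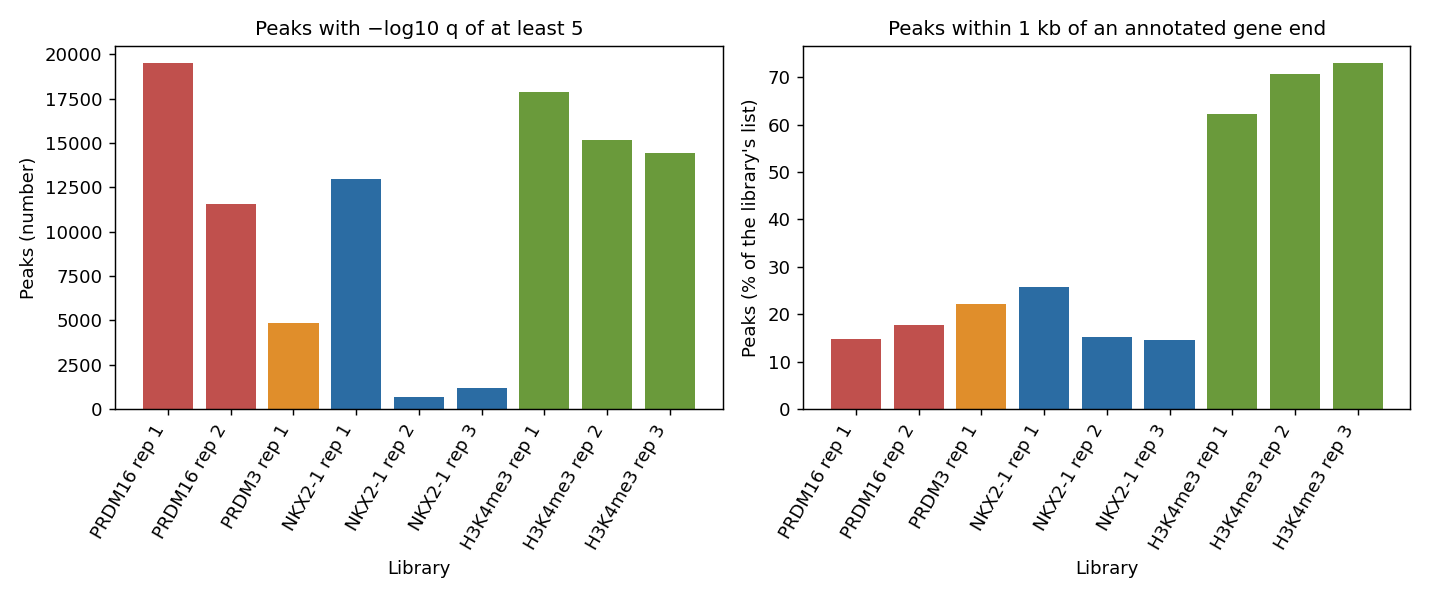
Bars give, for each of the 9 libraries, the number of peaks with a −log10 q of at least 5 (left) and the percentage of peaks within 1 kb of an annotated gene end (right). NKX2-1 replicates 2 and 3 had 668 and 1182 strong peaks against 12964 in replicate 1.

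H3K4me3 lay mainly at gene ends, whereas most NKX2-1 peaks lay elsewhere unless only peaks at a −log10 q of at least 5 were used. Of H3K4me3 peaks, 68.6% ± 5.60 (SD, n = 3) were within 1 kb of an annotated end of a protein-coding gene, against 18.5% ± 6.26 (SD, n = 3) of NKX2-1 peaks. The difference, −50.1 percentage points, was larger than the spread between libraries, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow. Within the first series the values were 62.3% for H3K4me3 and 25.8% for NKX2-1. Within the second they were 70.7% and 72.9% for H3K4me3 and 15.2% and 14.7% for NKX2-1. With only peaks at a −log10 q of at least 5, 68.1% ± 14.0 (SD, n = 3) of NKX2-1 and 70.2% ± 4.35 (SD, n = 3) of H3K4me3 peaks were at gene ends. The difference was then −2.11 percentage points (exact permutation p = 1). The NKX2-1 lists then held 12964, 668 and 1182 peaks, and each list counts equally in the mean. With the 20000 strongest peaks of each library the NKX2-1 share was 34.9% ± 6.92 (SD, n = 3). The difference from H3K4me3 was −33.7 percentage points (exact permutation p = 0.1). NKX2-1 regions found in at least 2 libraries were near gene ends in 46.0% of cases, against 3.81% after random shifts. The corresponding shares were 28.3% for PRDM16 and 22.3% for PRDM3 regions.

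H3K4me3 was more frequent at ends of alveolar and epithelial genes than of other genes. The mark was present at 20 of 24 AT1 genes, 20 of 24 AT2 genes, 23 of 27 lung epithelial transcription factor genes, 22 of 26 surfactant lipid synthesis genes and 19 of 20 epithelial junction and keratin genes. It was also present at 19 of 20 housekeeping genes. About 55.7% of other genes carried it, and each of these 6 lists was higher (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted exact p between 0.000892 and 0.0117 over 16 lists). It was less frequent at genes of mesenchymal (6 of 20), endothelial (5 of 18), and immune and blood cells (4 of 20), with adjusted exact p of 0.0321, 0.0364 and 0.00592. It was also less frequent at liver (1 of 18, adjusted exact p = 0.000161), neuron (3 of 18, adjusted exact p = 0.00486), airway secretory (3 of 15, adjusted exact p = 0.0118) and neuroendocrine genes (4 of 16, adjusted exact p = 0.0299). Ciliated (13 of 19), basal (3 of 10) and brown fat genes (7 of 12) did not pass this test.

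Libraries of the same target shared positions far above chance. Pairs of H3K4me3 libraries overlapped in 96.9% of the shorter list on average, 43.1 times the mean of shifted lists. Pairs of NKX2-1 libraries overlapped in 22.6%, an 8.63-fold excess. By pair, these were 23.8% for replicates 1 and 2, 28.2% for replicates 1 and 3, and 15.7% for replicates 2 and 3. The PRDM16 libraries, made with different antibodies, overlapped in 48.5%, a 10.1-fold excess. Pairs of libraries of different factors within the first series lay above or below that share. Of PRDM3 peaks, 52.8% overlapped PRDM16 replicate 1 (11.6-fold), 45.7% PRDM16 replicate 2 (14.4-fold) and 44.8% NKX2-1 replicate 1 (18.5-fold). Of 52685 peaks of NKX2-1 replicate 1, 33717 overlapped PRDM16 replicate 1 (11.9-fold) and 28977 overlapped replicate 2 (14.7-fold). Of H3K4me3 replicate 1 peaks, 80.9% overlapped NKX2-1 replicate 1 (18.4-fold), 85.1% PRDM16 replicate 1 (9.80-fold) and 65.5% PRDM3 (16.4-fold). Overlap within the first series was thus not particular to libraries of the same target. At a −log10 q of at least 5, pairs of NKX2-1 libraries overlapped in 76.5% (96.4-fold) and the PRDM16 libraries in 69.8% (39.9-fold). NKX2-1 replicates 2 and 3 then held only 668 and 1182 peaks, against 11551 in PRDM16 replicate 2, so these shares are not comparable. With the 20000 strongest peaks of each library the overlaps were 31.6% for NKX2-1 and 54.5% for PRDM16. With shifts of only 5 to 50 kb the excess was 6.10-fold for NKX2-1, 4.71-fold for PRDM16 and 15.8-fold for H3K4me3. Each two-sided shift permutation p was 0.002 for pairs of the same target, the smallest that 1000 draws can give, and 0.0198 for pairs of different targets, the smallest for 100 draws.

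PRDM16 and PRDM3 regions overlapped NKX2-1 regions far above chance, in a series that mapped where the 3 proteins bind. Of 39386 PRDM16 regions, 14314 (36.3%, Wilson 95% interval 35.9% to 36.8%) overlapped an NKX2-1 region, against 0.895% after shifts, a 40.6-fold excess. Of 52248 PRDM3 regions, 13744 (26.3%, 25.9% to 26.7%) did so, a 30.7-fold excess. PRDM16 regions overlapped PRDM3 in 52.2% of cases (51.7% to 52.7%), a 25.3-fold excess. Of 23795 NKX2-1 regions, 12062 (50.7%) overlapped regions of both PRDM16 and PRDM3, 61.2 times the shifted share. Each permutation p was 0.002. The intervals cover counting error only, and the shares varied with the libraries and peaks used. Leaving out an NKX2-1 library also required a region in both remaining ones. Without NKX2-1 replicate 1 the share over NKX2-1 was 17.0% for PRDM16 and 12.4% for PRDM3. With 1 PRDM16 library alone, whose peaks are not replicated, it was 19.4% without replicate 1 and 14.9% without replicate 2, and the share over PRDM3 was 29.2% and 23.1%. At a −log10 q of at least 5 the shares over NKX2-1 were 12.9% for PRDM16 and 14.5% for PRDM3, and with NKX2-1 regions in all 3 libraries 16.3% and 11.8%. The number of shared regions was 5927 without NKX2-1 replicate 1, 9561 without replicate 2, 8248 without replicate 3 and 17277 with replicate 1 alone, an alternative chosen after seeing the data. It was 618 at a −log10 q of at least 5, 4722 with the 20000 strongest peaks of each library and 5772 with NKX2-1 regions in all 3 libraries. Over the alternatives the excess ranged from 16.3-fold to 119.7-fold for PRDM16 with NKX2-1, from 14.0-fold to 130.7-fold for PRDM3 with NKX2-1, and from 10.4-fold to 102.1-fold for PRDM16 with PRDM3. For regions shared by all 3 proteins it ranged from 24.0-fold with shifts of 5 to 50 kb to 196.9-fold at a −log10 q of at least 5. Of single NKX2-1 libraries, the alternatives included only replicate 1. Replicates 2 and 3 alone gave PRDM16 and PRDM3 regions an excess of 9.40-fold to 13.1-fold.

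PRDM regions overlapped the NKX2-1 library of their own series more often than the others, a difference that 1 against 2 libraries cannot test. PRDM16 regions overlapped peaks of NKX2-1 replicate 1 in 65.4% of cases, replicate 2 in 27.7% and replicate 3 in 32.4% (41.8% ± 20.6, SD, n = 3). PRDM3 regions did so in 44.8%, 20.3% and 24.0% (29.7% ± 13.2, SD, n = 3). Every one of these shares exceeded its shifted value, by 9.40-fold at the least, with a permutation p of 0.0198, the smallest that 100 draws allow. The second series held no PRDM library, so no value within that series can be given. With the 20000 strongest peaks of each library the PRDM16 shares were 76.5%, 40.3% and 43.5%, or 49.7, 40.2 and 41.3 times the shifted shares. For PRDM3 they were 55.4%, 25.7% and 28.9%, or 40.1, 30.0 and 31.4 times. NKX2-1 replicate 1 also held more strong peaks than replicates 2 and 3, so series and strength cannot be told apart here.

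Overlap was also found at sites without H3K4me3. Of 23392 PRDM16 regions that overlapped no H3K4me3 peak, 3815 (16.3%, 15.8% to 16.8%) overlapped an NKX2-1 region, a 62.7-fold excess. Of 35826 such PRDM3 regions, 3230 (9.02%, 8.72% to 9.32%) did so, a 36.6-fold excess. Both permutation p were 0.002. These shares were lower when a library was left out, which also changed the rule for a region. Without NKX2-1 replicate 1 they were 3.66% (855 regions) and 2.12% (760), without replicate 2 10.5% and 5.94%, and without replicate 3 9.22% and 5.05%. With unreplicated PRDM16 peaks the share was 7.15% without PRDM16 replicate 1 (4356 of 60936) and 5.14% without replicate 2 (4694 of 91347). With NKX2-1 regions in all 3 libraries the shares were 3.22% and 1.90%, and at a −log10 q of at least 5 they were 2.18% (63 regions) and 2.93% (54). Over the alternatives the excess ranged from 19.05-fold to 369.7-fold for PRDM16 and from 15.9-fold to 445.9-fold for PRDM3. Of single NKX2-1 libraries, these alternatives included only replicate 1. The excess with replicates 2 and 3 alone was lower. It was 7.41-fold and 6.78-fold for distal PRDM16 regions, and 4.65-fold and 4.31-fold for distal PRDM3 regions. Here too replicate 1 of NKX2-1 gave the higher share, 49.5% of distal PRDM16 regions against 12.4% and 14.4% for replicates 2 and 3. For distal PRDM3 regions the shares were 25.7%, 7.35% and 8.64%. Of the 20000 strongest peaks of each library, those outside H3K4me3 were also compared. NKX2-1 replicate 1 overlapped PRDM16 replicates 1 and 2 in 43.1% and 44.8%, and the PRDM16 libraries overlapped each other in 42.2%. NKX2-1 replicate 1 overlapped NKX2-1 replicates 2 and 3 in 13.2% and 12.9%, and those replicates overlapped each other in 4.25%.

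**Figure D2:**
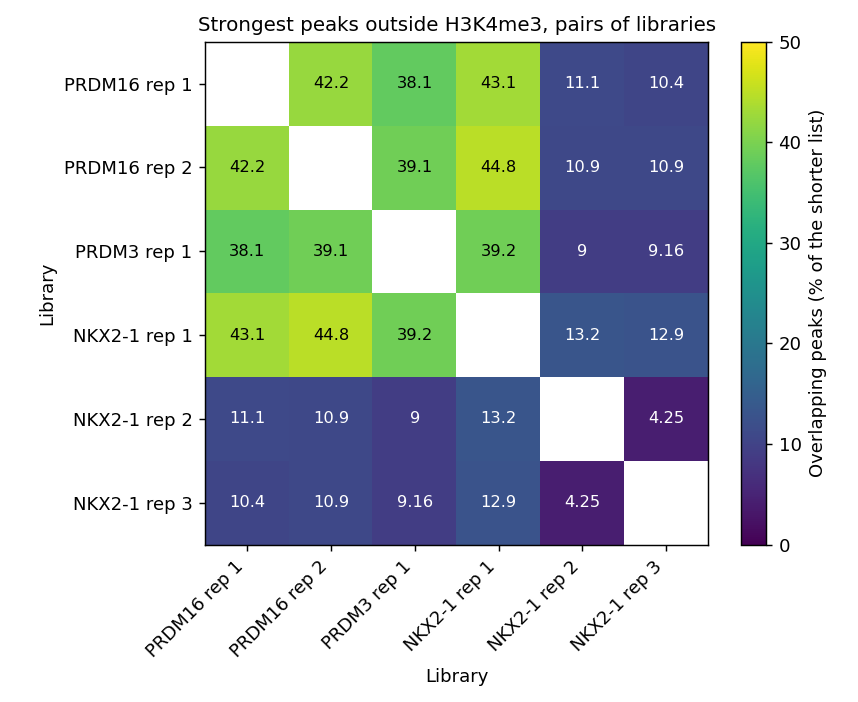
Each cell gives the percentage of the shorter list that overlaps the other, for pairs of the 6 factor libraries, using those of the 20000 strongest peaks of each library that lie outside H3K4me3. NKX2-1 replicate 1 shared 44.8% with PRDM16 replicate 2 and 13.2% with NKX2-1 replicate 2.

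PRDM16 peaks over an NKX2-1 region were higher than the rest. In the rabbit antibody library their median log2 fold enrichment was 2.69 over 16649 peaks, against 1.52 over the other 94791. In the sheep antibody library it was 2.29 over 15333 peaks, against 1.64 over 63704. The differences, 1.17 and 0.65, each had a two-sided permutation p of 1e-05 over peaks, the smallest that 100000 draws give, and peaks are not replicates. When rabbit antibody peaks were ranked by fold enrichment in 10 equal groups, 0.494% of the lowest group and 64.7% (63.8% to 65.6%) of the highest overlapped NKX2-1. For the sheep antibody these were 5.57% and 61.2%, and for PRDM3 17.0% and 72.9%. Across the lower groups the shares went up and down in all 3 libraries. Counted from the lowest, they rose without a break from group 5 for the rabbit antibody and PRDM3, and from group 7 for the sheep antibody. At a −log10 q of at least 5 the difference was 0.56 in the rabbit antibody library (permutation p = 1e-05) and −0.05 in the sheep antibody library (permutation p = 0.0727).

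NKX2-1 and PRDM peaks lay over H3K4me3 regions in shares that differed by less than the spread between libraries. These were 21.5% ± 7.76 (SD, n = 3) of NKX2-1 peaks and 20.7% ± 6.42 (SD, n = 3) of PRDM peaks (exact two-sided permutation p = 0.8, with 0.1 the smallest possible). The difference of 0.795 percentage points was −3.68 without NKX2-1 replicate 1, −2.05 without PRDM16 replicate 1 and −0.537 with the 20000 strongest peaks of each library. At a −log10 q of at least 5 it was 31.2 percentage points (exact permutation p = 0.1), with 82.5% ± 15.3 (SD, n = 3) of NKX2-1 peaks over H3K4me3. Within the first series the shares were 30.5% for NKX2-1, 15.0% and 19.4% for PRDM16, and 27.7% for PRDM3. The second series held NKX2-1 only.

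AT1 genes were the most completely covered cell type list. All 24 AT1 genes had a linked NKX2-1, a linked PRDM16 and a linked PRDM3 region, and 19 had a region shared by all 3 proteins. Among other genes 50.6%, 58.6%, 66.7% and 34.5% had one (adjusted exact p = 2.64e-06, 3.99e-05, 0.000468 and 0.000106). These and the following list tests were Fisher's exact tests, two-sided. Benjamini-Hochberg adjustment was over 64 tests of 16 lists and 4 region sets unless stated otherwise. At Scnn1g, which encodes a subunit of the epithelial sodium channel, a shared region lay inside the gene, 132 bases from its end (chromosome 7, 121734240 to 121734866). NKX2-1 fold enrichment there was 7.50 ± 5.30 (SD, n = 3), and PRDM16 fold enrichment was 23.7 and 5.05 in replicates 1 and 2. At Gprc5a (chromosome 6, 135065560 to 135066646) NKX2-1 reached 7.50 ± 5.23 (SD, n = 3), PRDM16 19.3 and 13.7, and PRDM3 12.2. Col4a3, a basement membrane collagen gene, had a shared region 8826 bases outside the gene (chromosome 1, 82577649 to 82578543; NKX2-1 9.80 ± 10.1, SD, n = 2 libraries with a peak). Krt7, a keratin gene, had one 57 bases from its end (NKX2-1 8.81 ± 5.77, SD, n = 2).

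AT2 genes were also covered more often than other genes. NKX2-1 regions were linked to 19 of 24, PRDM16 and PRDM3 regions to 23 each, and shared regions to 14 (adjusted exact p = 0.0165, 0.000424, 0.00545 and 0.0371). Cxcl15, a lung chemokine gene, carried a shared region 86 bases from its end (chromosome 5, 90794172 to 90794725), with NKX2-1 fold enrichment of 6.99 ± 5.13 (SD, n = 3) and PRDM16 fold enrichment of 9.53 and 10.5. Muc1, a membrane mucin gene, had one 658 bases away (NKX2-1 6.83 ± 4.33, SD, n = 3). Dlk1 had one outside H3K4me3, 32135 bases from the gene (NKX2-1 7.67 ± 5.20, SD, n = 2). Lyz2, a lysozyme gene, had no linked region of any of the 3 proteins. Surfactant lipid synthesis genes followed, with 22, 25, 24 and 20 of 26 covered by NKX2-1, PRDM16, PRDM3 and shared regions (adjusted exact p = 0.00218, 0.000204, 0.0151 and 0.000113). Fasn (fatty acid synthase), which stands in both lists, had NKX2-1 fold enrichment of 7.84 ± 4.08 (SD, n = 2) in a region inside the gene (chromosome 11, 120823490 to 120824701). Elovl6, a fatty acid elongase gene, had 9.06 ± 8.29 (SD, n = 2) in a region inside the gene and outside H3K4me3 (chromosome 3, 129621145 to 129621414). Chka (8.04 ± 6.86, SD, n = 2) and Elovl5 (6.91 ± 4.62, SD, n = 2) were the other leading members, and Lpin1 had no region.

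Genes of lung epithelial transcription factors had the highest share of shared regions among the 16 lists. All 27 had NKX2-1, PRDM16 and PRDM3 regions, and 25 had a shared one (adjusted exact p = 4.99e-07, 1.51e-05, 0.000242 and 2.86e-08). By the mean over the NKX2-1 libraries with a peak, the leading members were Id2 (8.34 ± 5.39, SD, n = 2), Grhl2 (8.22 ± 2.18, SD, n = 3), Nfib (7.86 ± 4.98, SD, n = 3) and Tead4 (7.73 ± 6.33, SD, n = 2). A mean that lacks replicate 2 or 3 is raised by the higher fold enrichments of replicate 1. In replicate 1 alone the values were 13.1 at Nfib, 12.2 at Tead4, 12.2 at Id2 and 9.36 at Grhl2. The Nfib region lay inside the gene and outside H3K4me3 (chromosome 4, 82304149 to 82304749). The genes of the 3 proteins themselves had shared regions. Nkx2-1 had 8 NKX2-1, 11 PRDM16, 21 PRDM3 and 4 shared regions, and the leading shared one lay inside the gene (chromosome 12, 56535289 to 56536384; NKX2-1 4.84 ± 0.830, SD, n = 3). Mecom had 7, 14, 21 and 4 such regions, and its leading one lay 5558 bases inside the gene (chromosome 3, 30503728 to 30504676), with NKX2-1 fold enrichment of 7.14 ± 5.30 (SD, n = 3) and PRDM16 of 18.3 and 9.67. Prdm16 had 6, 12, 10 and 3, led by a region inside the gene and outside H3K4me3 (chromosome 4, 154360091 to 154360463). NKX2-1 fold enrichment there was 4.74 ± 3.25 (SD, n = 2), and PRDM16 was 5.02 and 3.78. PRDM3 was 2.62 there, below that library's median of 3.39. The Nkx2-1 and Mecom regions overlapped H3K4me3. In the Nkx2-1 region PRDM3 was 5.67 and PRDM16 was 2.52 and 3.91, the 2.52 of replicate 1 being below that library's median of 2.87.

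**Figure D3:**
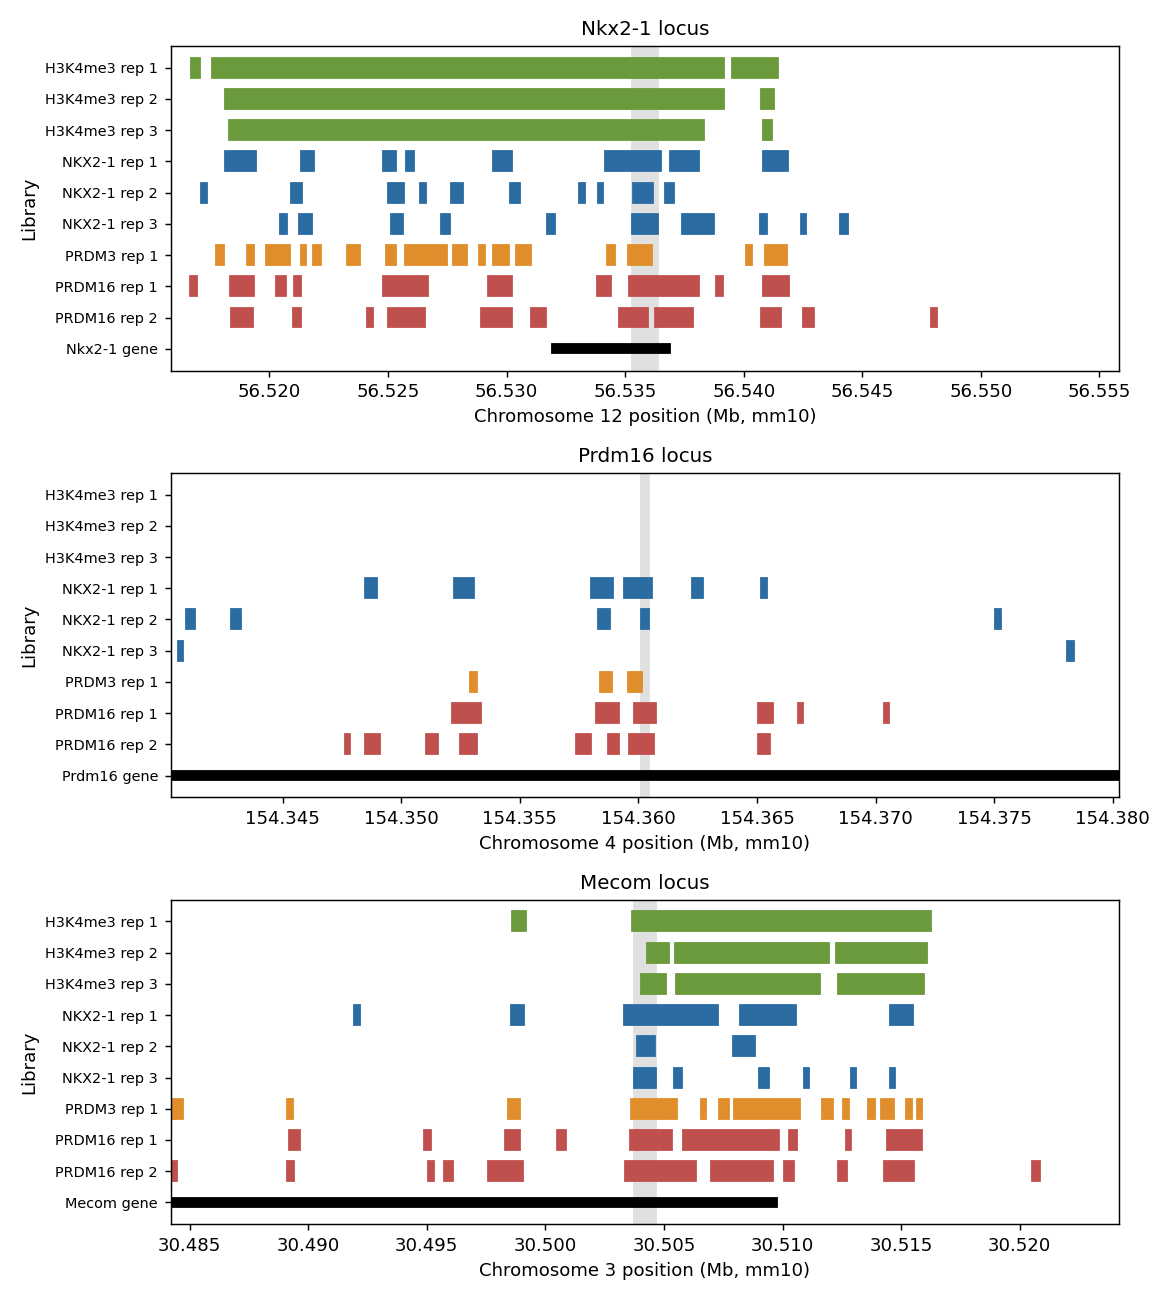
Boxes mark the peaks of each of the 9 libraries in 40 kb around the leading shared region (grey band) of Nkx2-1, Prdm16 and Mecom, with position in Mb on mm10 along the x axis and the annotated gene as a black bar. The Prdm16 region lay outside H3K4me3 and held no peak of NKX2-1 replicate 3.

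Epithelial junction and keratin genes were covered in 19 of 20 cases by each protein and in 16 by shared regions (adjusted exact p = 0.000242, 0.00183, 0.0166 and 0.000242). Esrp1, an epithelial splicing regulator gene, had NKX2-1 fold enrichment of 9.64 ± 7.62 (SD, n = 3), and Cldn4, a claudin gene, 7.38 ± 7.17 (SD, n = 3). PRDM16 fold enrichment in that Cldn4 region was 29.3 and 7.61. Esrp2 (6.97 ± 4.09, SD, n = 3) and Cldn7 (6.78 ± 2.95, SD, n = 3) followed. Ciliated cell genes were called for PRDM3 (18 of 19, adjusted exact p = 0.0165) and shared regions (12 of 19, adjusted exact p = 0.0313), but not for NKX2-1 (12) or PRDM16 (16). A region inside Dynlrb2, a dynein light chain gene, and outside H3K4me3 had NKX2-1 fold enrichment of 11.4 ± 8.82 (SD, n = 3), PRDM16 of 17.2 and 10.6, and PRDM3 of 14.9. Rfx3, a ciliogenic transcription factor gene, had NKX2-1 fold enrichment of 8.90 ± 8.51 (SD, n = 3). Housekeeping genes were called for NKX2-1 (17 of 20, adjusted exact p = 0.00835) and not for PRDM16 (16), PRDM3 (16) or shared regions (11). Among them Polr2a had NKX2-1 fold enrichment of 6.34 ± 2.96 (SD, n = 3), and Eef1a1 and Tbp had no region.

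Genes of several other cell types were covered less often than other genes, and for the rest no difference passed the test. Mesenchymal genes had fewer NKX2-1 regions (4 of 20, adjusted exact p = 0.0165) and fewer shared regions (1 of 20, adjusted exact p = 0.0108). No difference passed the test for PRDM16 (11) or PRDM3 (17). The 1 mesenchymal gene with a shared region was Pdgfra (NKX2-1 5.55 ± 4.45, SD, n = 2), and Fgf10 and Postn had no region of any protein. Immune and blood genes had fewer NKX2-1 (5 of 20), PRDM3 (8) and shared regions (1, at Klf1), with adjusted exact p of 0.0496, 0.0346 and 0.0108, and 8 PRDM16 regions. Liver genes had fewer NKX2-1 (2 of 18), PRDM16 (3) and shared regions (0), with adjusted exact p of 0.00237, 0.0018 and 0.00251, and 8 had a PRDM3 region. Neuroendocrine genes had fewer shared regions (1 of 16, at Ddc, adjusted exact p = 0.0346), with 5, 10 and 10 for NKX2-1, PRDM16 and PRDM3. Lists called lower thus numbered 3 for NKX2-1, 1 for PRDM16, 1 for PRDM3 and 4 for shared regions. In that order they numbered 2, 1, 0 and 4 with span-matched random lists, and 6, 4, 2 and 4 with a gene end within 1 kb. At a −log10 q of at least 5, or among genes with H3K4me3 at an end, 0 were called lower in each set. The NKX2-1 set then held only 1415 regions, and few genes of these lists carried H3K4me3, so lower shares could hardly be called. With NKX2-1 replicate 1 alone at this threshold, chosen after seeing the data, some lists were called lower. They were mesenchymal (2 of 20), endothelial (2 of 18), immune and blood (2 of 20) and liver genes (0 of 18). Their adjusted exact p over 16 lists were 0.0191, 0.0265, 0.0191 and 0.00115.

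With all peaks, no test was passed by airway secretory (7, 7, 10 and 4 of 15), basal (5, 7, 5 and 2 of 10), endothelial (6, 12, 14 and 2 of 18), neuron (8, 13, 16 and 4 of 18) or brown fat genes (8, 8, 7 and 6 of 12), in the order NKX2-1, PRDM16, PRDM3 and shared. Shared regions near single members of these lists included those at Aldh1a1 (NKX2-1 5.56 ± 0.913, SD, n = 3) and Scgb1a1, the club cell secretory protein gene (2.71 ± 0.449, SD, n = 2), in the airway secretory list. In the endothelial list Flt1, a VEGF receptor gene, had NKX2-1 fold enrichment of 5.43 ± 1.92 (SD, n = 2), and in the neuron list Map2 had 7.33 ± 3.82 (SD, n = 3). In the basal list Icam1 had 3.90 ± 2.50 (SD, n = 2). In the brown fat list, taken from PRDM16 work in other tissue, Ebf2 had 8.92 ± 9.89 (SD, n = 3) and Zfp516 had 8.68 ± 8.83 (SD, n = 2), and Cpt1b and Dio2 had no region. Whether lists differed between a PRDM protein and NKX2-1 could hardly be tested. For AT1 and transcription factor genes 0 members had a region of only 1 of the compared proteins, which fixed the outcome, and in the other lists few had. In 32 Fisher's exact tests 0 passed, with 0 at an unadjusted p under 0.05, which does not show that the proteins were alike.

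**Figure D4:**
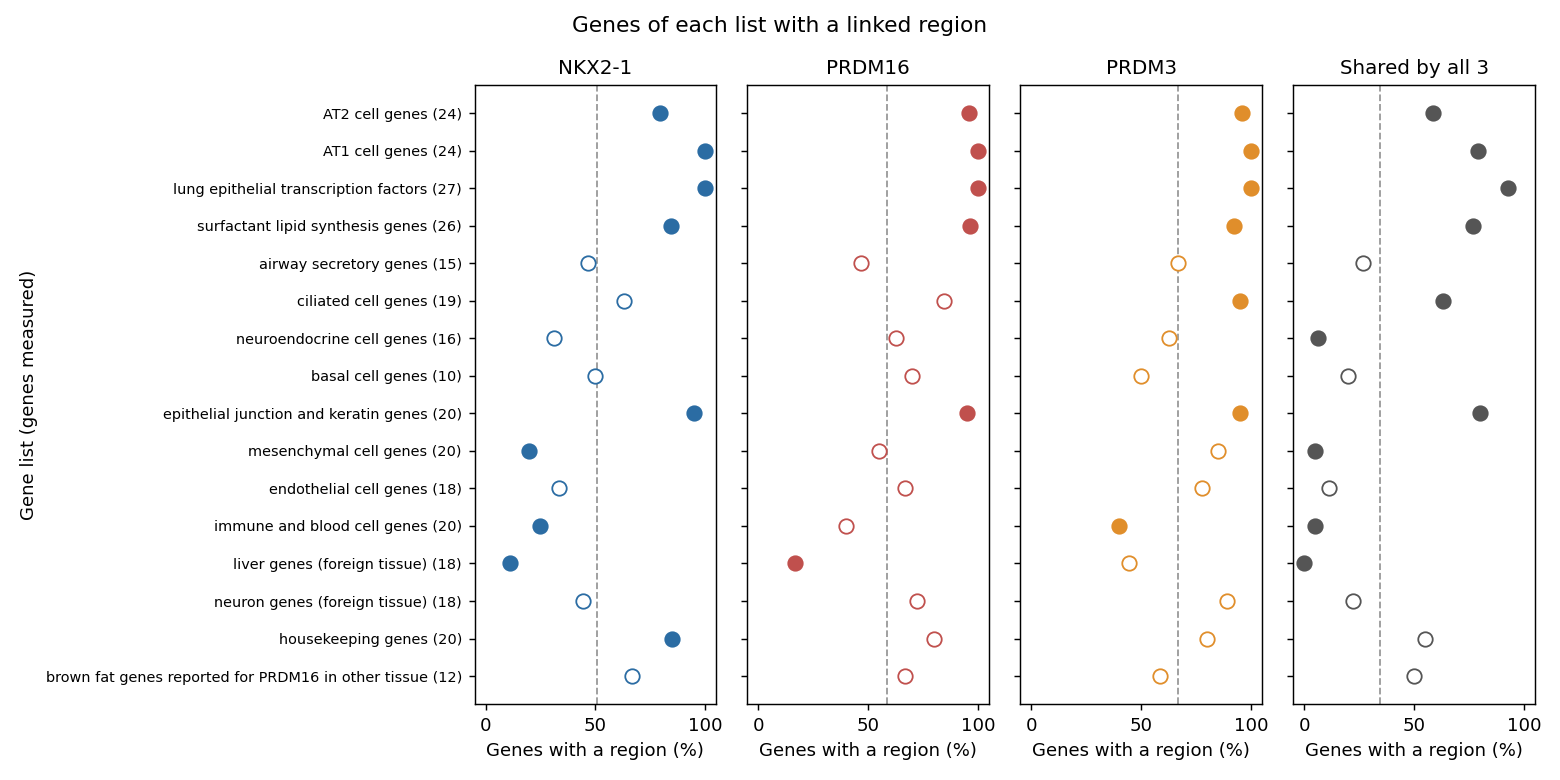
Points give the percentage of measured genes in each of 16 lists that had a linked region of NKX2-1, PRDM16, PRDM3 or all 3, with the share of other genes as a dashed line. Filled points passed the adjusted threshold of 0.05, such as AT1 genes at 100% for NKX2-1, and open points did not.

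The list calls were made against all genes, many of which lacked H3K4me3. When only genes with H3K4me3 at an end were compared, 0 lists were called for NKX2-1, PRDM16 or PRDM3 by Fisher's exact test (2, 4 and 1 at an unadjusted p under 0.05). For shared regions 1 list was called, lung epithelial transcription factors with 21 of 23 genes against 54.9% of other genes (adjusted exact p = 0.0151), and 4 passed at an unadjusted p under 0.05. Among other genes with H3K4me3, 76.9% had an NKX2-1 region, 81.5% a PRDM16 region and 85.3% a PRDM3 region, which left little room above them. Without PRDM16 replicate 2, 3 lists were called for PRDM16 instead of 5, and with the 20000 strongest peaks 3 instead of 6 for shared regions. At an unadjusted p under 0.05 these were 8 against 6, and 6 against 6. With peaks at a −log10 q of at least 5, 5 lists each were called for PRDM16 and PRDM3, of which 5 and 4 were called with all peaks. PRDM16 regions were then linked to 18 of 24 AT1 and 24 of 27 transcription factor genes, and to 3 of 20 housekeeping genes, against 24.4% of other genes for the first 2 lists. PRDM3 regions were linked to 18 of 24 AT1, 18 of 27 transcription factor and 1 of 20 housekeeping genes. Brown fat genes were also called for PRDM3 at this threshold (6 of 12, adjusted exact p = 0.0324), and for PRDM16 with the 20000 strongest peaks (8 of 12, adjusted exact p = 0.0306). At this threshold NKX2-1 had 1 called list, AT1 genes (6 of 24, adjusted exact p = 0.0176), and shared regions had 0 (1 at an unadjusted p under 0.05). With NKX2-1 replicate 1 alone, which holds most of the strong peaks, 5 lists were called higher at this threshold. They were AT1 (20 of 24, adjusted exact p = 0.00014), AT2 (16 of 24), transcription factor (23 of 27), surfactant lipid (20 of 26) and junction genes (14 of 20). With the threshold and the H3K4me3 background together, PRDM16 had 3 called lists, which were AT1, transcription factor and surfactant lipid genes. PRDM3 had 4, which were AT1, transcription factor, junction and brown fat genes (5 of 7, adjusted exact p = 0.0395). NKX2-1 replicate 1 alone then had 0 (2 at an unadjusted p under 0.05). The use of replicate 1 alone and of both restrictions together was chosen after seeing the data. Where choices were combined, adjustment was over the 16 lists of 1 region set and not over 64 tests. Those counts are therefore not directly comparable with the others.

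The shared regions with high mean ranks of fold enrichment over the 6 factor libraries included those linked to Cyhr1, Tbc1d17, Cdca3, Sertad2, Rps6ka5, Kdm4a, Stk40, 9130023H24Rik and Ppp2r5a. Each of these regions overlapped H3K4me3, and each lay within 1 kb of a gene end except the one inside Sertad2. The region at Kdm4a, a histone demethylase gene (chromosome 4, 118179262 to 118180667), had NKX2-1 fold enrichment of 18.3 ± 11.8 (SD, n = 3). PRDM16 fold enrichment there was 24.3 and 8.93, and PRDM3 fold enrichment was 15.1. In each of these regions NKX2-1 replicate 1 had the highest NKX2-1 fold enrichment, and fold enrichments of different libraries are on scales set by each library's own background.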

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

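Every list held some peaks on unplaced or unlocalised scaffolds, which no comparison used. There were 49 and 35 in the PRDM16 libraries, 35 in PRDM3, 31, 70 and 94 in the NKX2-1 libraries, and 18, 9 and 8 in the H3K4me3 libraries. These peaks made up from 0.0440% (PRDM16 replicate 1) to 0.118% (NKX2-1 replicate 3) of a list. Control libraries were not analysed here, and no explanation was tested.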

How the results depend on the processing

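Alternatives chosen after seeing the data were NKX2-1 replicate 1 alone, gene lists without each library, a link to the gene body, and combined choices. The overlap folds kept their direction and their side of the threshold under every alternative run. The folds over shifts ranged from 16.3 to 119.7 for PRDM16 with NKX2-1 and from 14.0 to 130.7 for PRDM3 with NKX2-1. NKX2-1 replicates 2 and 3 alone, which were not among these alternatives, gave lower folds of 9.40 to 13.1. The shared regions numbered 618 at a −log10 q of at least 5, 4722 with the 20000 strongest peaks and 5772 with regions in all 3 libraries. Leaving out 1 library, which for NKX2-1 also required a region in both others, gave 5927 to 13797. Stricter lists hold fewer peaks by construction. The difference in H3K4me3 overlap between NKX2-1 and PRDM peaks, 0.795 percentage points in a design that could not reach 0.05, was 31.2 at a −log10 q of at least 5 (exact p = 0.1, the smallest possible), −0.537 with the 20000 strongest peaks, and −3.68 to 4.28 when 1 library was left out, being −3.68 without NKX2-1 replicate 1 and −2.05 without PRDM16 replicate 1. The mean PRDM16 signal difference fell to 0.25 at a −log10 q of at least 5. It stayed past the threshold with the rabbit antibody (0.56, permutation p = 1e-05) and not with the sheep antibody (−0.05, permutation p = 0.0727). The cause was not tested.

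With genes carrying H3K4me3 as the background, 0 lists were called for NKX2-1, 0 for PRDM16, 0 for PRDM3 and 1 for shared regions. At a −log10 q of at least 5, NKX2-1 had 1 and shared regions 0, and NKX2-1 replicate 1 alone had 5 called higher. Shared regions had 3 with the 20000 strongest peaks. Leaving out 1 PRDM16 library gave 3 to 7 lists for PRDM16, the 3 being without replicate 2. Shared regions fell from 6 lists to 4 with span-matched random lists, a gene end within 1 kb, the gene body link, or no NKX2-1 replicate 1 (7, 4, 4 and 4 at an unadjusted p under 0.05). NKX2-1 fell from 6 to 4 with a gene end within 1 kb or the 20000 strongest peaks (4 and 5 unadjusted), and PRDM3 from 6 to 4 with the gene body link (6 unadjusted). With a −log10 q of at least 5 and the H3K4me3 background together, PRDM16 had 3. With NKX2-1 replicate 1 alone added to both choices, NKX2-1 had 0 (2 at an unadjusted p under 0.05). Combined choices were adjusted over 16 lists and the other counts over 64 tests. The cause was not tested. Of other genes with H3K4me3, 76.9% to 85.3% already had a region of a given protein.

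Replicate number as a block left the gene-end difference at −50.1, with an exact p of 0.25, the smallest 3 pairs allow. Deviations of same-numbered NKX2-1 and H3K4me3 libraries correlated over 6954 regions by 0.268, 0.0946 and 0.168, so the numbers were not taken to pair samples. NKX2-1 replicate 2 correlated best with H3K4me3 replicate 3 (0.0956). All 5 correlations within a letter series were positive and all 4 between series negative (−0.215 to −0.124), so deviations went with the series, though centring on 3 libraries forces some opposite signs. The 4 motif results and their alternatives, and the alternative with all transcript starts, were not run. Unknown depth limits any reading of the weak NKX2-1 replicates 2 and 3.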

Other observations

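The tests on the widest H3K4me3 regions, on PRDM regions without NKX2-1, on mesenchymal genes and on NKX2-1 replicate 1 peaks in PRDM libraries were chosen only after the result was seen. The widest H3K4me3 regions lay at lung epithelial transcription factor, AT2 and AT1 genes more often than at other marked genes. Among the 500 widest H3K4me3 regions (3953 to 21051 bases), one lay at 15 of 23 marked transcription factor genes, against 4.12% of other marked genes (Fisher's exact test, two-sided, adjusted exact p = 1.21e-14 over 16 lists). One also lay at 8 of 20 marked AT2 genes (adjusted exact p = 6.34e-06) and 5 of 20 marked AT1 genes (adjusted exact p = 0.00654). The widest region of all, 21051 bases, lay at Nkx2-1 (chromosome 12, 56518121 to 56539171), followed among the listed genes by Foxa2 (12332 bases), Gata6 (11847) and Foxp2 (10654). Prdm16 (9029 bases) and Mecom (6496) had one too. Surfactant lipid (4 of 22, adjusted exact p = 0.0508), junction and keratin (3 of 19, adjusted exact p = 0.142), ciliated (0 of 13), airway secretory (0 of 3) and housekeeping genes (1 of 19, at Actb) did not pass the test, nor did the other lists.

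Genes with the most shared regions were Mtcl1 and Svil, with 9 each, followed by Hes1, Hopx, Myh9, Rai14, Zfp516 and Zfp608 with 8, and Camk2g and Ccn1 with 7. The counts were not adjusted for locus span, and intersecting libraries can split 1 peak into several regions. Hopx is an AT1 marker and Hes1 a target of Notch signalling. PRDM16 regions that overlapped PRDM3 and no NKX2-1 peak of any library numbered 2495. They were linked to 10 of 27 transcription factor genes (adjusted exact p = 0.000116), 7 of 24 AT1 and 7 of 24 AT2 genes (both adjusted exact p = 0.005), and 7 of 26 surfactant lipid genes (adjusted exact p = 0.0063), against about 6.92% of other genes. The other lists did not pass, among them junction and keratin (2 of 20), neuroendocrine (3 of 16) and housekeeping genes (1 of 20). These were two-sided Fisher's exact tests adjusted over 16 lists. These genes were named and this comparison was chosen after their values were seen.

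The list calls may only follow H3K4me3-marked gene ends, since they were mostly lost among marked genes. With regions outside H3K4me3, 5 of the 6 lists called for shared regions were called again for each of NKX2-1, PRDM16 and PRDM3, which argues against marked gene ends as the whole source. AT1 genes had such regions in 18, 22 and 21 of 24 cases, and housekeeping genes in 0, 8 and 7 of 20. For PRDM3, mesenchymal (16 of 20) and neuron genes (15 of 18) were also called outside H3K4me3. Calls outside H3K4me3 were against all genes and were not matched on locus span. A link of distal sites with active genes in general, or with locus span, thus stays open. Background cutting of accessible chromatin, without IgG libraries to compare, remains open here.

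Strong distal peaks of different antibodies in the first series overlapped more than NKX2-1 libraries of different series did. A candidate explanation is weak enrichment of NKX2-1 replicates 2 and 3. Of distal NKX2-1 replicate 1 peaks, split by fold enrichment in 10 equal groups, 53.3% (51.6% to 54.9%) of the strongest group and 9.70% of the weakest were found in replicates 2 or 3. This decides nothing, since the PRDM libraries gave the same contrast (92.9% and 29.3% in PRDM16 replicate 1). Sites cut whatever the antibody cannot be told apart from shared binding. Distal NKX2-1 peaks without a PRDM peak, only 670, were found in replicates 2 or 3 with odds ratios of 1.32, 0.947 and 1.10 relative to PRDM peaks without NKX2-1, and each 95% interval included 1. The library series cannot be told apart either: H3K4me3 peaks of replicate 1 alone favoured NKX2-1 replicate 1 by a ratio of 2.03 over peaks of all replicates, but 79.6% of the latter were found in replicates 2 or 3, which held their ratio to at most 1.26.

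PRDM3 regions were linked to 17 of 20 mesenchymal genes, which was not called. Outside H3K4me3 they were linked to 16 of 20, which was (adjusted exact p = 0.0125), as were neuron genes (15 of 18). Weak peaks are a candidate explanation that stays open. At a −log10 q of at least 5, 10.0% of mesenchymal genes (2 of 20, Wilson 95% interval 2.79% to 30.1%) had a PRDM3 region, against 15.6% of other genes. Outside H3K4me3 it was also 2 of 20, against 4.57%, too few to decide. Cells of other types that passed the EpCAM selection were not excluded. H3K4me3 lay at 15 of 58 mesenchymal, endothelial and immune genes and 1 of 18 liver genes (Fisher's exact test, one-sided, p = 0.0568), and at 5 of 17 mesenchymal genes with a PRDM3 region and 1 of 3 without, too few to decide. A biological explanation was not tested.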
